A study of Drosophila melanogaster with 2 samples.

How the data were processed

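Small RNAs of 18 to 30 nt were gel-purified from total RNA of hand-dissected ovaries of 3 to 5 day old Drosophila melanogaster females and sequenced on an Illumina instrument, per the labels' protocols. The series holds 2 libraries, 1 from pelo1/+ ovaries and 1 from peloPB60/1 ovaries. Each library came with 2 tables, 1 for miRNAs and 1 for piRNAs. The deposited values are raw counts of reads per feature, whole numbers with no normalization, and each table lists features with at least 1 count. A feature listed for 1 library only was given 0 counts in the other. The miRNA tables name hairpins, so both arms of a hairpin share 1 count. The piRNA tables name transposon and repeat sequences, many of them with the tag of another Drosophila species, and genomic intervals. Bowtie 0.12.7 and the genome build BDGP5 are named in the submitters' processing notes without their roles. The miRNA and repeat references, the mismatches allowed, the treatment of reads with several matching places, strand, adapter trimming and total reads per library are not given in the sources used here. Reads that match near-identical hairpins (mir-2a-1 and mir-2a-2) or related transposon sequences (TART and Dyak\TART) may have been split between them, and single values of such features are uncertain.

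The genotype came from the genotype label of each sample. There was 1 library per genotype, so no difference has a replicate check, no p-value was computed, and every comparison is between 2 libraries. The pelo transcript itself is not measured by these tables, so they hold no check of the genotype labels.

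Counts were divided by the total of their own table and given as CPM, the reads of a feature in 1000000 reads of its table. The total of a table is the depth of a read class and not of the library. For each feature with at least 50 counts summed over both libraries, the log2 ratio of peloPB60/1 over pelo1/+ was computed with 0.5 counts added to each count. Its 95% interval was the exact conditional (Clopper-Pearson) interval of the unmodified counts. These intervals cover counting error only, because sequenced reads carry no molecular identifiers here and biological spread is not measured. A feature was called higher or lower when it differed at least 2-fold and its interval excluded no difference. A count of 0 allows up to 3 counts, which is 1.65 and 1.50 CPM in the miRNA tables and 0.574 and 0.616 CPM in the piRNA tables of pelo1/+ and peloPB60/1. Profiles were compared by Pearson and Spearman correlation of log2 CPM across features, which are not independent replicates. The number of piRNA reads per miRNA read was taken from the totals.

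Lists of 12 miRNA groups and 6 transposon groups were fixed before the data were examined, as were the filters, the size rule, the rule for named features and the alternatives, apart from those said to be added after seeing the data. The groupings were made from general knowledge and not from these libraries. Of the listed names, mir-iab-4, mir-iab-8, 17.6 and protop had no feature of that name, and a feature called 176 was not taken for 17.6. For lists with at least 3 members past the filter, the median log2 ratio was placed among 10000 random lists of the same size matched on abundance decile. That percentile describes these 2 libraries. The random lists could hold the list's own members, and 108 hairpins in 10 deciles leave few others to draw from. This can draw miRNA percentiles toward the middle. For the K-box and somatic lists the median of the random lists equalled that of the list (-0.41 and -0.37). Per read class, the text names the 10 most abundant features, the 8 called features with the largest difference in each direction, and up to 4 abundant members of each list. Features named beyond this rule are said to be so, and elements whose name is a bare number are described by their values only. The name transib was matched to each numbered transib element. The comparison of hairpins within genomic clusters was added after the data were seen. Hairpins on the same strand with at most 10000 bp between neighbours formed a cluster. Neighbours were taken from the Ensembl annotation of BDGP6, in which 232 of 235 hairpins were found. That build differs from BDGP5, so none of its coordinates are given. The coordinates of intervals are printed as the deposited tables give them, and BDGP5 is the build named in the notes.

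Alternatives covered scaling (the total of both tables, edgeR 4.0.16 TMM factors, DESeq2 1.42.0 median-of-ratios factors, upper quartiles, and the miRNA total for piRNAs), count filters of 1, 10 and 200, size rules of 1.5-fold and 4-fold, an added count of 1, and leaving out the 10 most abundant features. edgeR and DESeq2 served for scaling factors only. The computation was tested on simulated Poisson counts drawn from the real features and totals. With no change simulated, 0 of 110 miRNA and 2 of 439 piRNA features were called. Of features changed 3-fold, 100% of 11 miRNAs and 91.9% of 62 piRNA features were called in the right direction. Of those changed 1.5-fold, 8.33% of 12 miRNAs and 21.5% of 65 piRNA features were called so. The simulated counts held no spread between libraries, so they check the computation and not how far unreplicated libraries differ. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and R 4.3.3 were used. In the piRNA tables, a feature called Repeat, which names no element, held 1.49% and 1.30% of the counts and was kept in the totals. A feature called TART-CTART-ATART-BTirant appears to be several names run together and is printed as listed.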

Results

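Small RNA counts were compared between ovaries of pelo1/+ females, which carry 1 normal copy of pelo, and ovaries of peloPB60/1 females, which carry the mutant alleles PB60 and 1. The gene pelo (pelota) encodes a factor that releases stalled ribosomes and is required in the female germline. miRNAs are short regulators of mRNAs cut from hairpin precursors, and piRNAs guide Piwi proteins to transposon transcripts in gonads. The miRNA tables held 1819781 reads on 234 hairpins in pelo1/+ and 1999224 reads on 235 hairpins in peloPB60/1. The piRNA tables held 5229331 reads on 1127 features in pelo1/+ and 4872519 reads on 1097 features in peloPB60/1. Each genotype was represented by 1 library, so every value below is a difference between 2 libraries with no replicate check. Intervals cover counting error only, apart from the bootstrap intervals of the closing part.

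The first comparison asked how the miRNA profile differed between the genotypes. miR-989, a follicle cell miRNA with a known role in border cell migration, was the most abundant miRNA in peloPB60/1, at 443523 CPM against 173893 CPM in pelo1/+. This was a 2.55-fold difference (log2 ratio 1.35, 95% interval 1.34 to 1.36), and miR-989 took 44.4% of all miRNA reads in peloPB60/1. miR-306 led in pelo1/+ with 20.2% of the reads and had a log2 ratio of -0.84. miR-996, miR-9c and miR-184, the last with a known role in female germline development, differed little, with log2 ratios of -0.23, 0.23 and 0.19. miR-994, miR-308 and miR-305 were abundant in pelo1/+ and were 12.9-fold, 8.63-fold and 3.47-fold lower in peloPB60/1. miR-9b was 7.61-fold higher. The remaining miRNA among the 10 most abundant, miR-8, had a log2 ratio of -0.40.

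Of 108 hairpins with at least 50 summed counts, 17 were at least 2-fold higher in peloPB60/1, 34 were at least 2-fold lower and 57 were neither. The largest positive difference was that of miR-984, at 168.7 CPM in pelo1/+ and 5772 CPM in peloPB60/1, a 34.2-fold difference. Its neighbours miR-982 and miR-303 were 14.5-fold and 14.0-fold higher, the former from 7 and 119 reads. miR-2a-1 was 9.83-fold, miR-34 8.12-fold, miR-2b-2 6.59-fold and miR-316 4.36-fold higher. At the other end, miR-79 was at 4978 CPM in pelo1/+ and 156.1 CPM in peloPB60/1, 31.8-fold lower (log2 ratio -4.99, 95% interval -5.16 to -4.83). miR-1013 was 12.3-fold lower from 117 and 10 reads, and miR-993 was 9.24-fold lower from 71 and 8 reads. miR-314, miR-13b-1 and miR-311 were also lower, with log2 ratios of -3.17, -3.10 and -2.91. miR-2a-1, miR-2b-2 and miR-13b-1 each have a near-identical second copy that can share their reads. Summed over both copies, miR-2a was 2.40-fold and miR-2b 6.32-fold higher, and miR-13b was at 1.41 times its pelo1/+ share.

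The split between higher and lower hairpins moved with the scaling. It was 23 higher and 29 lower with the total of both tables, and 23 and 28 with either TMM or median-of-ratios factors. With miR-989 left out of the totals it was 27 and 24. Across the 108 hairpins the 2 profiles had a Pearson correlation of 0.91 and a Spearman correlation of 0.88. The 10 most abundant hairpins held 82.2% of the reads in pelo1/+ and 86.6% in peloPB60/1.

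**Figure D1:**
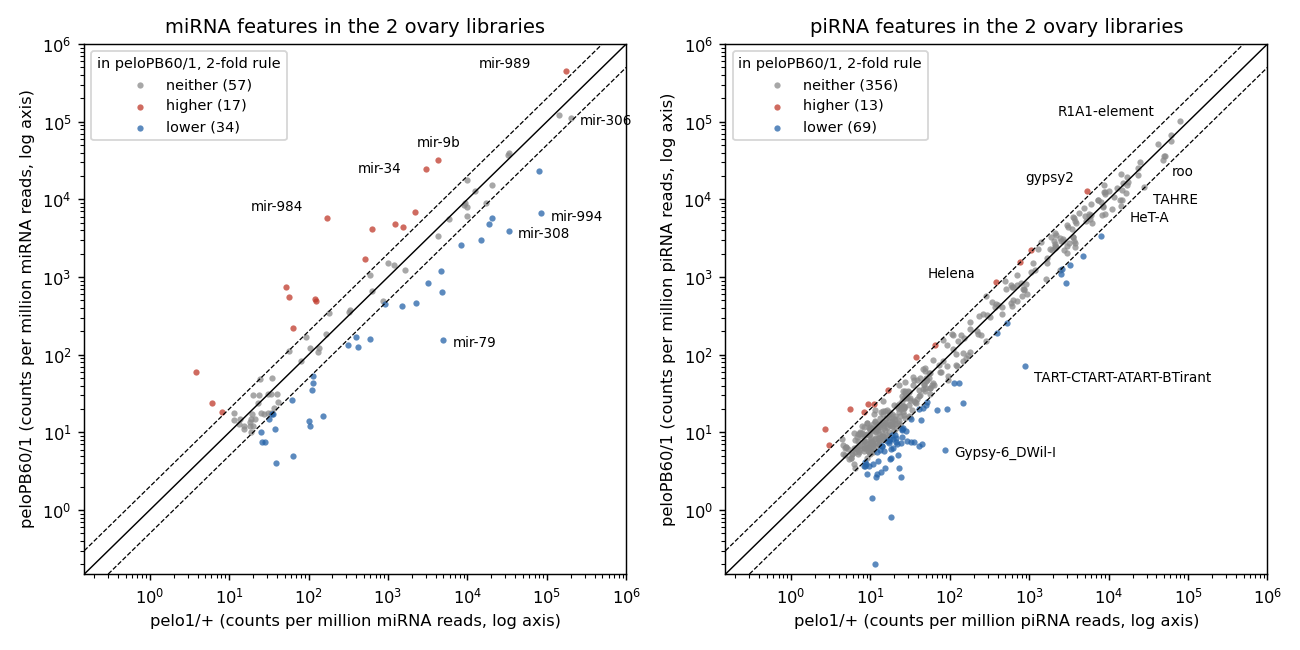
CPM of each feature with at least 50 summed counts in the pelo1/+ library (x axis) and the peloPB60/1 library (y axis), both on log axes, for miRNA hairpins (left) and piRNA features (right). The solid line marks equal values and the dashed lines 2-fold differences; 51 of 108 hairpins (17 higher, 34 lower) and 82 of 438 piRNA features (13 higher, 69 lower) were called.

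Among 8 miRNAs linked to the female germline and early oogenesis, 5 were lower (4 with TMM or median-of-ratios scaling), 1 was higher and 2 were neither. bantam, a growth regulator also needed in germline stem cells, was 3.84-fold lower, and miR-312 was 5.02-fold lower. The other lower members were miR-310, miR-311 and miR-313, so 4 of the 5 came from 1 genomic cluster. miR-278, outside the naming rule, was 3.90-fold higher, and miR-7 and miR-184 had log2 ratios of 0.06 and 0.19. The list's median log2 ratio was -1.58, at the percentile 4.52 of random lists. The random lists drew hairpins singly, whereas 4 of the 8 members share a cluster. Both the median and the percentile therefore lean on that 1 cluster and do not describe 8 separate miRNAs. In the follicle cell and late oogenesis list, miR-989 was higher, miR-994 was lower and miR-318 was at 9252 and 8912 CPM. Its median was -0.05 (percentile 68.9) or 0.20 with TMM scaling, while its pooled reads, most of them from miR-989, were 1.71-fold higher.

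The let-7 complex, a set of hormone-timed miRNAs, was split. let-7 was 3.27-fold lower, miR-125 was 2.88-fold higher and miR-100 had a log2 ratio of 0.93, which passed 2-fold with the total of both tables, TMM and median-of-ratios scaling. Its median was 0.93 (percentile 58.6), whereas its pooled reads were at 0.726 of the pelo1/+ share. The miR-9 list, which includes the cluster members miR-79 and miR-306, had 2 higher, 1 lower and 2 uncalled members. Its median was 0.23 (percentile 74.4), and its pooled reads were at 0.756 of the pelo1/+ share. The K-box family had 9 members past the filter, of which 2 were higher, 4 were lower and 3 were neither, with a median of -0.41 (percentile 48.3). Its pooled reads, which in pelo1/+ were mostly those of miR-308, were at 0.316 of the pelo1/+ share. The lower members miR-2b-1 and miR-13b-1 are copies whose sums with the second copy, given above, were not lower. miR-11 and miR-13b-2, both uncalled, had log2 ratios of -0.41 and 0.63.

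Of 10 miRNAs that are abundant in somatic tissues, 1 was higher, 3 were lower and 6 were neither, with a median of -0.37 (percentile 49.6). The listed markers of other tissues were scarce apart from miR-1, the muscle miRNA. It was at 2218 CPM in pelo1/+ and 6899 CPM in peloPB60/1, 3.11-fold higher. The ovary is wrapped in a muscle sheath, which dissected ovaries contain. The other muscle miRNA, miR-133, had 12 reads in each library. No neuronal miRNA passed the filter, and the 4 listed held 49 and 74 reads. The 14 listed members of testis-expressed clusters held 0.0340% and 0.0401% of the reads. Clusters outside the list were not counted, among them that of miR-982, miR-303 and miR-984, which was higher in peloPB60/1. These shares therefore do not measure all miRNAs of other tissues. Of the 6 past the filter, miR-962 was 3.44-fold higher, miR-963 and miR-960 were lower (1 lower member with the total of both tables, TMM or median-of-ratios scaling), and the others, miR-961 and miR-964 among them, were uncalled, with a list median of -0.21 (percentile 73.3) that was 0.04 with TMM and 0.02 with median-of-ratios scaling. Mirtrons, which are spliced rather than cut from their host, had 3 lower and 1 uncalled member. These were miR-1013, miR-1010 and miR-1005, and miR-1006 at -0.84, with a median of -1.29 (percentile 21.9). miR-10, the 1 Hox miRNA found, had a log2 ratio of -0.77 from 56 and 36 reads. The miR-309 cluster, known from early embryos, held 94 and 100 reads, with no member past the filter.

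Hairpins that lie next to each other in the genome are usually cut from 1 primary transcript, so differences within clusters were also listed. There were 16 clusters with at least 2 hairpins past the filter, holding 47 hairpins. In 13 of them the highest and lowest members differed more than 2-fold with intervals that did not overlap. In 5 of them 1 member was called higher and another lower. In the cluster of miR-9c, miR-306, miR-79 and miR-9b, the log2 ratios ran from -4.99 for miR-79 to 2.93 for miR-9b. In the cluster of miR-317, miR-277 and miR-34 they ran from -1.96 for miR-277 to 3.02 for miR-34, with miR-317 at -0.10. miR-318 and miR-994 differed by 3.64 log2 units in their change, and miR-92a and miR-92b, of related sequence, by 3.58. Members went the same way in the cluster of miR-982, miR-303 and miR-984, all called higher. In the cluster of miR-310, miR-311, miR-312 and miR-313, all called lower, the uncalled members miR-991 and miR-992 had 0.62 and -0.89 from few reads. A factor common to a library does not alter these differences within clusters.

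**Figure D2:**
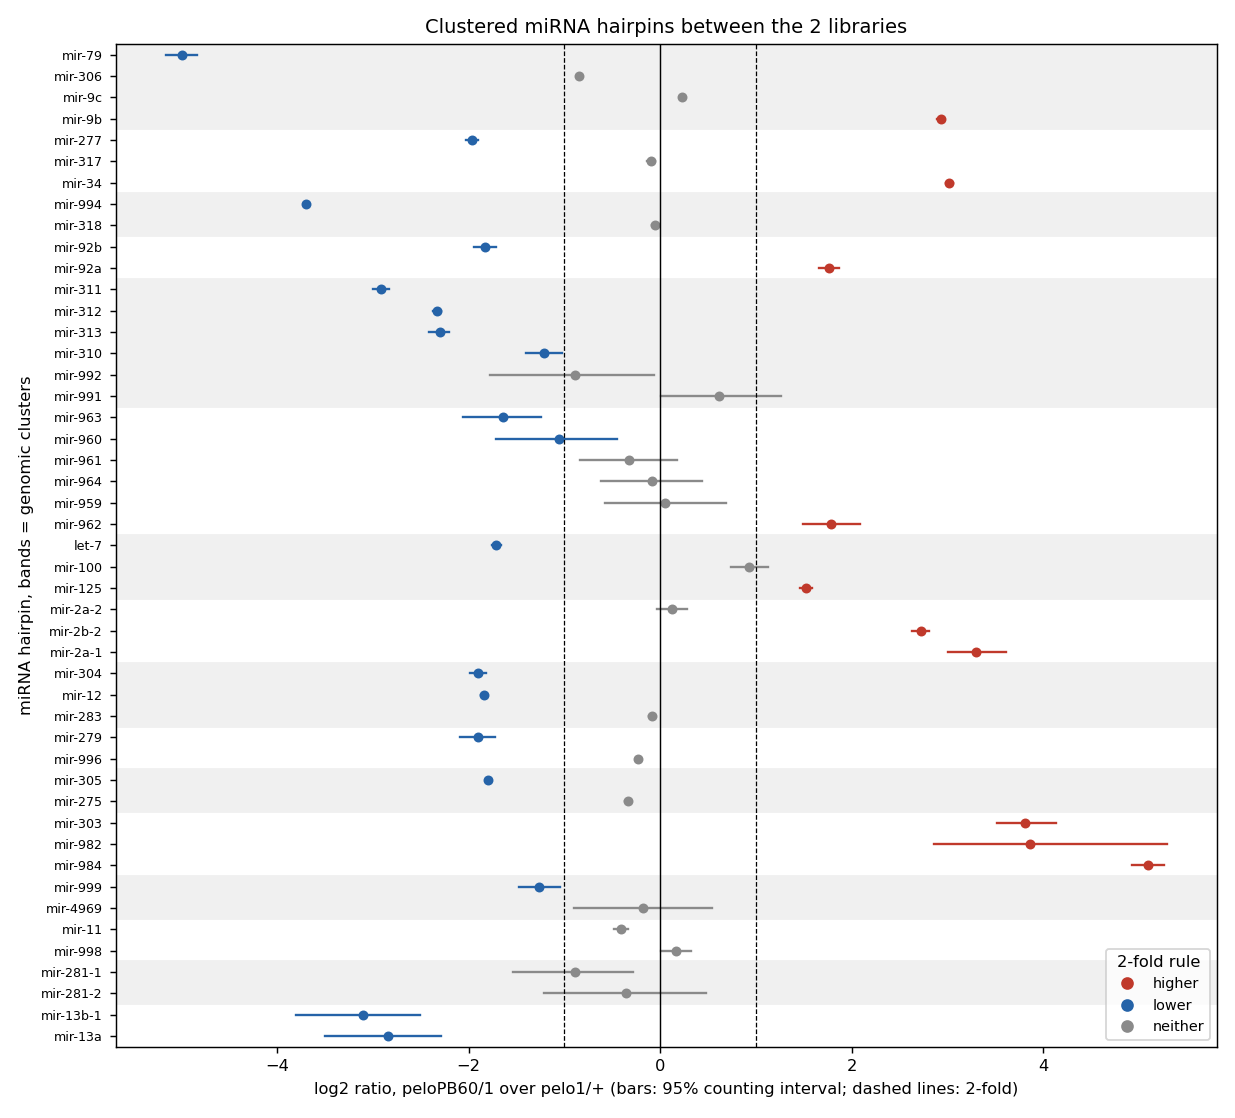
Log2 ratio of peloPB60/1 over pelo1/+ (x axis) for the 47 hairpins of 16 genomic clusters (y axis, clusters in alternating bands), with 95% counting intervals as bars and 2-fold differences as dashed lines. The widest spread was in the cluster of miR-79 (-4.99) and miR-9b (2.93), and the 3 hairpins miR-303, miR-982 and miR-984 lay together on the right.

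The next comparison asked how the piRNA profile differed between the genotypes. The 10 transposons with the most piRNA reads each differed by less than 1.5-fold between the libraries when scaled to the total of the table. R1A1-element, a retrotransposon that inserts into ribosomal DNA, led both, with 7.94% of the reads in pelo1/+ and 10.2% in peloPB60/1 (log2 ratio 0.36, 95% interval 0.35 to 0.37). Max-element, GATE, X-element and TART had log2 ratios of 0.15, 0.30, 0.29 and 0.10, and F-element, Rt1a, Doc, Rt1b and roo had -0.13, -0.19, -0.45, -0.50 and -0.58. None of these 10 reached 2-fold. With the total of both tables roo, with the miRNA total roo, Rt1b and Doc, and with upper quartiles R1A1-element, Max-element, GATE, X-element and TART passed 1.5-fold. The sign flipped for Max-element and TART with the miRNA total, for F-element with TMM, median-of-ratios and upper quartile scaling, and for Rt1a and Doc with upper quartiles. Of the 94 features with at least 10000 summed counts, 69 were within 1.5-fold and 9 were called, 3 higher and 6 lower.

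Of 438 piRNA features with at least 50 summed counts, 13 were at least 2-fold higher in peloPB60/1, 69 were at least 2-fold lower and 356 were neither. Of the 233 tested features whose names carry the tag of another Drosophila species, 5 were higher and 48 lower. Of 52 genomic intervals 5 were higher and 9 lower, and of the 153 tested features with other names 3 were higher and 12 lower. With TMM scaling the split was 17 higher and 47 lower, with upper quartiles 50 and 31, and with the miRNA total 5 and 101. The Pearson correlation across the 438 features was 0.98 and the Spearman correlation 0.92. The SD of the log2 ratio among features with at least 1000 summed counts was 0.640 for 147 piRNA features and 1.99 for 53 miRNA hairpins. The 10 most abundant piRNA features held 46.8% and 45.9% of the reads in pelo1/+ and peloPB60/1.

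gypsy2 was the most abundant of the features higher in peloPB60/1, at 5359 and 12684 CPM, a 2.37-fold difference. Helena was 2.23-fold higher. The others among the 8 largest were rarer. They were Gypsy-22_DWil-LTR with 16 and 34 reads, 1 interval on 2R and 4 intervals of unplaced sequence. The largest difference among these was at 1613423 to 1615486 of U, 4.03-fold higher from 14 and 54 reads, and the interval on 2R, 327388 to 327660, was 2.13-fold higher from 44 and 88 reads. With the miRNA total Helena, Gypsy-22_DWil-LTR and the interval on 2R were under 2-fold, with log2 ratios of 0.92, 0.93 and 0.86. The feature listed as TART-CTART-ATART-BTirant was at 888.4 CPM in pelo1/+ and 72.0 CPM in peloPB60/1, 12.3-fold lower (log2 ratio -3.62, 95% interval -3.79 to -3.47). Gypsy-6_DWil-I was 14.4-fold lower from 454 and 29 reads, and Gypsy16-LTR_Dya 19.6-fold lower from 94 and 4 reads. Gypsy1-LTR_Dmoj, Gypsy17-I_Dya, Gypsy-7_DTa-LTR and Dbif\P-element_O were 8.94-fold, 6.42-fold, 6.90-fold and 6.15-fold lower. The interval 11706902 to 11707647 of the unplaced sequence Uextra had 59 reads in pelo1/+ and 1 in peloPB60/1 (log2 ratio -5.21, 95% interval -11.11 to -3.25).

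Of 52 tested members of the transposon lists, 1 was called. With the miRNA total 5 were called, all lower, and with upper quartiles 11, all higher, of which 5 were follicle cell elements, 3 germline LTR elements, 2 LTR elements of both compartments and 1 a DNA transposon. Among the 3 telomeric retrotransposons, which maintain fly chromosome ends, 0 were called. TAHRE was at 27611 and 14226 CPM (log2 ratio -0.96, or -1.02 with the total of both tables), HeT-A was at 14244 and 8290 CPM (-0.78), and TART was at 0.10. With the miRNA total both TAHRE and HeT-A were called lower, at -1.19 and -1.02. The median of the 3 was -0.78, at the percentile 0.520 of random lists, and it rested on TAHRE and HeT-A. Dyak\TART and TART_B1, which can share reads with TART, had log2 ratios of 0.18 and 0.18. TART-CTART-ATART-BTirant, whose name contains both TART and Tirant, had -3.62. Which of the named elements its reads came from is not known, so it was not counted as telomeric. Of 10 transposons that are mainly silenced in somatic follicle cells, 9 had a log2 ratio above 0 and gypsy had -0.29. With the miRNA total 6 were above 0, and with upper quartiles 10. gtwin, gypsy5 and Tabor had log2 ratios of 0.71, 0.65 and 0.52. The list's median was 0.46, at the percentile 97.9, and 0 of the 10 were called. The medians of both fixed lists kept their sign in all scalings and filters tried.

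Of 12 LTR elements that are mainly silenced in the germline, 8 were above 0 and 4 below. The median was 0.08 (percentile 38.5), or -0.16 with the miRNA total, from -0.58 for roo to 0.78 for invader1, and mdg3 and opus had -0.45 and -0.09. Of 4 LTR elements active in both compartments, mdg1 and blood had log2 ratios of 0.54 and 0.08 and the other two had 0.56 and -0.56, with a median of 0.31 (percentile 88.3). Of 11 non-LTR elements, Juan was called, 2.27-fold lower, or -0.69 on the log2 scale and uncalled with upper quartiles. It is outside the naming rule and is named because it was the 1 call among the lists. The median was -0.19 (percentile 9.61), or 0.31 with upper quartiles. Of 12 DNA transposons 0 were called, while 1 was lower with the total of both tables and with the miRNA total, and 1 higher with upper quartiles. The most abundant of them had a log2 ratio of -0.16, and transib2, Bari1 and hobo had -0.12, 0.68 and -0.28. Their median was -0.16 (percentile 30.6), or 0.02 with TMM scaling and 0.33 with upper quartiles.

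**Figure D3:**
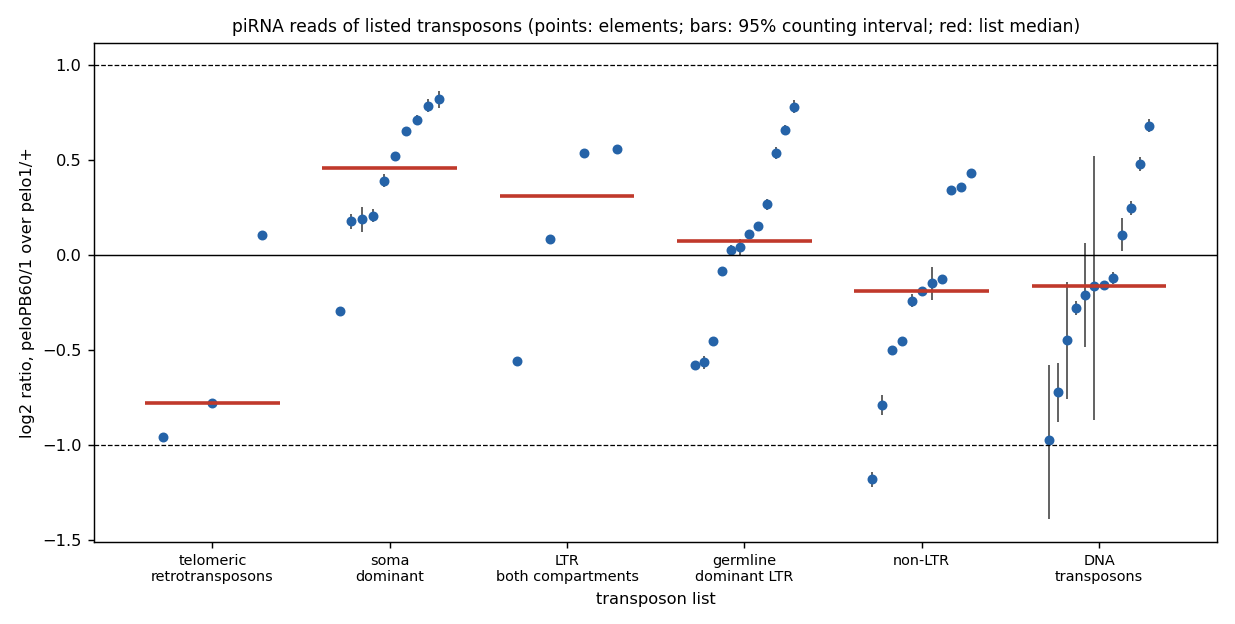
Log2 ratio of piRNA reads in peloPB60/1 over pelo1/+ (y axis) for the tested members of 6 transposon lists (x axis), with 95% counting intervals as bars, list medians in red and 2-fold differences as dashed lines. Medians ran from -0.78 for the 3 fixed telomeric elements to 0.46 for transposons silenced mainly in follicle cells, and Juan was the 1 element beyond 2-fold.

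The last comparison set piRNA reads against miRNA reads within each library. There were 2.87 piRNA reads per miRNA read in pelo1/+ and 2.44 in peloPB60/1, a ratio of 0.848 (95% interval 0.846 to 0.850). The direction rested on miR-989. With it left out, the values were 3.48 and 4.38 and the ratio was 1.26. Without the 10 most abundant miRNAs they were 14.8 and 14.7, a ratio of 0.993.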

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

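Leaving out miR-989, leaving out features named by other species or by intervals, upper quartiles for lists and named features, and the miRNA total for named features were alternatives chosen after seeing the data. No paired analysis was possible because each genotype has 1 library, and for the same reason no library could be left out. Of 153 values of the summary results under alternatives, 118 stayed within their range and 34 moved. The remaining 1 was the piRNA to miRNA ratio, which turned from 0.848 to 1.26 without miR-989, because that hairpin alone takes 44.4% of the miRNA reads of peloPB60/1. That ratio was 0.993 without the 10 most abundant miRNAs and 0.858 without the 10 most abundant piRNA features. List medians close to 0 changed sign too, for 5 of 14 lists under at least 1 alternative. These were DNA transposons (0.02 with TMM), germline LTR elements (-0.16 with the miRNA total), non-LTR elements (0.31 with upper quartiles), and the follicle cell and testis miRNA lists (0.20 and 0.04 with TMM). Of 457 values of named features, 0 changed sign among the called ones, 3 calls were lost, each of them with the miRNA total, and 12 were gained, 6 of them with upper quartiles. Many of these features were named for their large differences, so their calls say little about the rest. Of all 82 piRNA calls, 60 were kept with TMM, 68 with median-of-ratios and 44 with upper quartile scaling. Of all 51 miRNA calls, 45 were kept with TMM and 41 with miR-989 out of the totals. Scaling moved all log2 ratios of miRNAs by 0.17 (both tables), 0.25 (TMM), 0.23 (median of ratios) or -0.13 (upper quartiles), and those of piRNAs by -0.07, 0.18, 0.13 or 0.50 in that order and by -0.24 with the miRNA total.

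The miRNA counts of 17 higher and 34 lower became 8 and 11 at 4-fold, and 27 and 24 with miR-989 out of the totals, so that higher ones outnumbered lower ones. The piRNA counts of 13 higher and 69 lower became 50 and 31 with upper quartiles, again with more higher than lower, 7 and 25 at 200 summed counts, 37 and 124 at 1.5-fold, 1 and 18 at 4-fold, and 3 and 12 without the features named by other species or intervals. They were 5 higher and 101 lower with the miRNA total, 25 and 90 with a filter of 1 count, and 25 and 84 with a filter of 10 counts. Fewer or more features pass these rules by construction, and each scaling adds 1 common shift to all log2 ratios. Which shift is correct was not tested. With the miRNA total the telomeric median was -1.02 and that of DNA transposons -0.40. With upper quartiles the medians were 0.95 for follicle cell transposons, 0.80 for LTR elements of both compartments, 0.57 for germline LTR elements and 0.33 for DNA transposons, which is the common shift of that scaling. Pearson correlations were 0.94 and 0.84 for miRNAs and 0.97 for piRNAs, and Spearman correlations 0.82 for miRNAs and 0.95 and 0.96 for piRNAs, with filters of 10 or 200 counts. The 20 most abundant features held 94.2% and 94.4% of miRNA and 63.4% and 61.6% of piRNA reads. At these depths counting error is small beside 2-fold for abundant features. It is not for features near 50 summed counts, such as Gypsy-22_DWil-LTR (log2 interval 0.29 to 2.15 from 16 and 34 reads). The missing replicates limit every comparison.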

Other observations

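All tests in this part, and the features named in this paragraph, were chosen after the results were seen. The intervals in this part are bootstrap intervals over clusters, hairpins or features of these 2 libraries. They measure spread among features and not between ovaries. Among abundant transposons outside the lists, invader6 and invader3 were 3.50-fold and 2.55-fold lower in peloPB60/1. rooA, BS3 and gypsy8 were 2.33-fold, 2.28-fold and 2.04-fold lower. Besides gypsy2, the features Pifo_I and Gypsy20-I_Dya were 2.09-fold and 2.06-fold higher. gypsy2 and invader6 passed 2-fold under each scaling tried. gypsy8 did not with TMM (-0.85), median-of-ratios (-0.90) or upper quartile scaling (-0.54), and invader3 (-0.85), rooA (-0.73) and BS3 (-0.70) did not with upper quartiles. Pifo_I and Gypsy20-I_Dya did not with the miRNA total (0.83 and 0.80) or the total of both tables, where Gypsy20-I_Dya was at 0.97. Among miRNAs outside the report's groups, miR-12 and miR-304 were 3.58-fold and 3.73-fold lower while their neighbour miR-283 had a log2 ratio of -0.09.

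Neighbouring hairpins changed by different amounts, with a median range within clusters of 2.49 log2 units (bootstrap interval over 16 clusters 1.28 to 3.53). Random reassignment of the values among the 47 hairpins gave a median of 2.94, and 22.2% of 10000 reassignments were as low. That does not decide whether altered transcription of whole clusters had a part. Reads shared between near-identical hairpins cannot be the whole cause, since the range was 1.66 (interval 1.28 to 3.42, 8 clusters) without such families. Candidate explanations that stay open are capture that depends on sequence during library preparation, and cutting or decay of single hairpins changed by the genotype. The latter was not tested. The log2 ratios spread 3.10 times as widely among abundant miRNAs as among abundant piRNA features (interval 2.26 to 4.12). Capture predicts such a spread because piRNA features sum over many sequences. Altered cutting or decay of hairpins predicts it because the piRNA features are not hairpins. The wider spread therefore cannot tell these explanations apart.

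The median of follicle cell transposons lay above 0 and that of telomeric elements below it. No member of either list was called when scaled to the total of the table. With upper quartiles 5 follicle cell elements were called higher. Telomeric elements called lower numbered 1 with the total of both tables and 2 with the miRNA total. The telomeric median rested on TAHRE and HeT-A. As a hypothesis, the opposite signs of the list medians might reflect fewer germline cells in the mutant ovaries. Follicle cell transposons exceeded germline LTR elements by 0.38, with a bootstrap interval over elements of -0.07 to 0.79 that holds 0. Elements are not replicates of a genotype, so the hypothesis remains undecided. Differences in transposon content between the fly stocks were not tested and stay open, for the 12.3-fold lower TART-CTART-ATART-BTirant as well.

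Lower piRNA features outnumbered higher ones, although with upper quartiles 50 were higher and 31 lower. At 50 to 500 summed counts, the 202 features named for other species had a median log2 ratio of -0.39 and 45 of the lower calls. The 25 features with other names in that range had a median of -0.35 (interval -0.53 to -0.16), with 0 higher and 2 lower calls. The 128 such features above 500 counts had a median of 0.10, with 3 higher and 10 lower calls. A candidate explanation is less background on rarely hit features in the peloPB60/1 library, such as reads matched with mismatches. The median of -0.35 became -0.17 with TMM (interval -0.35 to 0.01) and 0.14 with upper quartiles (interval -0.03 to 0.33). These shifts cannot decide the question, since a scaling moves all features alike. The upper quartile of 1364 features also falls among rarely hit ones, as 438 had at least 50 summed counts and 243 at least 200. The 25 features had a lower median than the 128 above 500 counts, and no scaling can alter that difference. That difference does not tell background from other causes, so the explanation stays open. No biological explanation of the excess of lower features was tested.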
